A study of Arabidopsis thaliana with 14 samples.

How the data were processed

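Seeds of Arabidopsis thaliana, accession Ws-0, were sampled at the mature green stage from plants kept under continuous light. Per the labels' protocols, siliques were fixed in ethanol and acetic acid and embedded in paraffin, and compartments were isolated by laser capture on a Leica LMD6000. RNA was extracted with an RNaqueous Micro kit and DNase treatment, a few nanograms were amplified with WT-Ovation Pico, and the product was biotinylated with an FL-Ovation module and hybridised to Affymetrix ATH1 arrays. Whole seeds were captured in the same way from serial sections of seeds. The values are array intensities on a linear scale that the authors obtained from the scanned arrays with GCOS, per the submitters' processing notes. The GCOS version, the signal algorithm and the background correction are not given in the sources used here. The intensities were used as deposited. After 2% of the values were trimmed from each end, every array had nearly the same mean, as a scaling to a common mean leaves. Signals ranged from 0.242 to 578653, and 0 values were missing.

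All 14 arrays were used, in the 7 groups that the labels give, with 2 arrays each. The precision of every comparison is limited by this number of arrays. Values under a floor of 23.43, the median over arrays of the 20th percentile, were raised to it, and log2 was taken. A fold against a group at the floor is given as at least that fold. Of 22810 probe sets, 64 controls were left out, and 14252 were tested because both arrays of at least 1 group lay above their array's median. The platform table with the gene table given for this work assigned 13513 of the 22746 probe sets that are not controls to 1 gene, 503 to several genes and 8730 to no gene. Of the tested probe sets these were 7823, 298 and 6131, and 1097 had a gene symbol other than the locus. A gene with several probe sets was represented by its probe set for that gene alone with the highest mean log2 signal. Of 87 genes with several tested probe sets, 1 was called in both directions in the embryo comparison, 2 in the seed coat comparison and 0 elsewhere.

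A linear model with 1 mean per group was fitted to all 14 arrays (7 residual degrees of freedom) in limma 3.58.1 under R 4.3.3, with moderated variances that follow an intensity trend. Each of the 6 compartments was compared with the mean of the other 5. Further comparisons were micropylar against peripheral endosperm, chalazal endosperm against the mean of the other endosperm parts, chalazal seed coat against seed coat, and whole seeds against embryo. P-values were adjusted within a comparison by the Benjamini-Hochberg method and called under 0.05. A probe set was enriched in a compartment if it was called higher, by at least 1 on the log2 scale, in each of the 5 pairwise comparisons. Most comparisons share arrays, but the chalazal comparison within the endosperm shares none with that within the seed coat. The 6 differences of a probe set, each against the mean of the other 5 compartments, add up to 0. A high value in 1 compartment therefore lowers the differences of the others, and a low value raises them. These are not separate findings. Whether the chalazal difference itself differed between endosperm and seed coat was tested with an interaction contrast of the same fit. The overlap expected from independent lists is the product of both counts divided by the number of probe sets tested.

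Gene lists were tested with camera of limma, once with a preset correlation of 0.01 and once with the correlation estimated from the arrays, and adjusted over 9 lists and 10 comparisons, 90 tests in all. The 21 lists hold 321 loci, of which 55 are on probe sets named by the tables used. The lists tested, with at least 3 members tested each, were storage proteins (5 of 13 loci), LEA and desiccation proteins (9 of 19), photosynthesis (4 of 27), fatty acid and oil synthesis (4 of 22), flavonoids (3 of 19), glucosinolates (3 of 8), mucilage and integument (4 of 23), sugar and amino acid transport (3 of 18), and cell death and vacuolar proteases (7 of 12). Counts below are over the members tested, and a list result does not cover its other loci. With fewer members tested were cell division, endosperm markers, expansins and mannanases, heat shock proteins, lipid mobilisation, oil body proteins and maturation regulators. Embryo patterning, vascular markers, suberin and cutin, gibberellin metabolism and abscisic acid metabolism had none measured. Families of at least 8 members, read from symbols or from the chromosome, were added after the annotation was seen. They were 19, of which 17 were tested (170 tests).

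The groups, comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, for each compartment against the others, the 10 enriched genes with the largest difference, filled from those called higher, and the 5 lowest called lower. For each comparison of 2 tissues it takes the 8 highest and 8 lowest called. It adds 3 members of each called list, and genes known by a locus alone could be passed over for the next. Both readings, with any name and with a symbol, were followed, and some names were left out of the text. Members of lists that answer a marker question are given with their values.

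The alternatives fixed in advance were no floor (values under 1 raised to 1), a pseudocount in place of the floor, no filter, a filter at the 75th percentile, division by the array median, quantile normalization, shared probe sets left out, only the arrays of the groups compared, no intensity trend, no minimum for enriched probe sets, a fold minimum for calls, the replicate number as a block, each array left out in turn, and the estimated correlation. Scaling on 9 spike-in probe sets, both seed coat arrays left out, the families, and the settings for list counts and for the chalazal overlap and interaction were added after the data were seen. The fit was tested on simulated data with the group sizes of the study: of 100 probe sets changed by 1 on the log2 scale 3 to 12 were recovered, of 100 changed by 3 it was 84 to 94, and of 14042 unchanged ones 2 to 12 were called. A simulated list shifted by 1 had adjusted p of 2.1e-07 to 1.9e-05 with the preset correlation and 0.024 to 0.087 with the estimated, and 0 of 50 unchanged lists were called. The simulated probe sets varied independently, so this cannot show how often unchanged lists of correlated genes are called. In the data the estimated correlation ran from -0.1236 (glucosinolates) to 0.308 (photosynthesis). Figures were drawn in Python 3.11.15 with matplotlib 3.10.9 and numpy 2.4.6.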

Results

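Transcript levels were measured in laser-captured compartments of Arabidopsis thaliana seeds (accession Ws-0) at the mature green stage. At this stage the cotyledons of the embryo reach the chalazal end of the seed and the seed coat layers are still intact. The chalazal end is where the seed is attached to the mother plant and supplied from it, and the micropylar end is where the root of the embryo points. The 14 arrays fell into 7 groups of 2. The 6 compartments were the embryo proper, the micropylar, peripheral and chalazal parts of the endosperm, the seed coat and its chalazal region. The remaining group, whole seeds, was captured from sections of complete seeds at the same stage. Each array gave an intensity for 22810 probe sets, and 14252 of them were tested. An array has no read depth, and the number of arrays limits the precision. The labels call the 2 arrays of a group biological replicates but do not say which plants or seeds each came from. Captures of different compartments may come from the same seeds, and p-values measure the spread between these samples. Below, a signal is given as the mean ± SD of n = 2 arrays, a log2 difference as the estimate ± SE, and an adjusted p is that of limma. Where 1 array of the lower group was raised to the floor of 23.4, the difference is a lower limit too, even without "at least" beside it. Among the 355 calls on named genes, both arrays of the group lay beyond the mean of the groups compared with it in 355. They lay beyond every one of their arrays in 274. The genes were named because they were called on these same arrays, so the first count was nearly fixed by that choice and is no support for the calls.

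Replicate arrays resembled each other closely, and those of the seed coat the least. Across probe sets, which are not independent replicates, the log2 signals of 2 replicates had a Pearson correlation of 0.812 in seed coat, 0.864 in chalazal seed coat, 0.878 in chalazal endosperm, 0.906 in embryo, 0.908 in micropylar endosperm, 0.912 in whole seeds and 0.929 in peripheral endosperm. Micropylar and peripheral endosperm were the closest pair of compartments (0.867 to 0.902 between their arrays), and embryo and chalazal seed coat were far apart (0.392 to 0.432). The first principal component, with 36.9% of the variance, placed chalazal seed coat and seed coat on 1 side (91.9 to 152.5) and embryo and endosperm on the other (-88.51 to -17.32). The second, with 17%, ran from embryo (-78.96 and -72.66) to chalazal endosperm (73.96 and 91.51). Median signals ranged from 133.8 on micropylar endosperm replicate 2 to 202.6 on seed coat replicate 2. The bacterial and phage spike-in probe sets, 9 hybridisation controls, had geometric mean signals of 82310 and 117000 on the seed coat arrays against 33510 to 54630 on the others. Ratios of the 3' to the 5' control probe sets were 4.1 to 16.9 for actin, 2.71 to 7.10 for GAPDH and 5.45 to 10 for ubiquitin.

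The embryo was compared with the mean of the other 5 compartments to find the transcripts that set it apart. STOMAGEN (AT4G12970), a secreted peptide that promotes the formation of stomata, had a signal of 4047 ± 1504 in the embryo and at most 32.0 ± 42.1 in any other compartment (log2 difference 7.12 ± 0.54, at least 139.6-fold, adjusted p = 1.2e-07). AT1G62500 reached 58030 ± 29020 against 66.4 ± 55.3 to 799 ± 404 elsewhere (8.09 ± 0.47, adjusted p = 9.1e-09). YAB3 (AT4G00180), a YABBY transcription factor of the abaxial side of lateral organs, was at least 47.85-fold higher (5.58 ± 0.70, adjusted p = 2.4e-05), and ATOEP16-2 (AT4G16160), a protein of the outer plastid envelope, 4.58 ± 0.41 higher on the log2 scale (adjusted p = 6.6e-07). Higher values were also called for PPDK (AT4G15530), pyruvate orthophosphate dikinase (4.01 ± 0.56, at least 16.15-fold), SNZ (AT2G39250), an AP2-type repressor of flowering (3.90 ± 0.58, at least 14.88-fold), NET4B (AT2G30500), an actin-binding protein (3.58 ± 0.35), and ALDH11A3 (AT2G24270), an aldehyde dehydrogenase (3.61 ± 0.40). In the other direction, AT4G01610, a cathepsin B-like protease, was at least 138.9-fold lower in the embryo (-7.12 ± 0.30, adjusted p = 2.6e-10), and the sugar transporter SWEET7 (AT4G10850) at least 90.51-fold lower (-6.50 ± 0.31, adjusted p = 1.1e-09), with signals of 541.7 ± 111.3 to 5363 ± 2189 in the other compartments.

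The seed reserve genes that could be tested were high in the embryo. Of 13 storage protein loci in the list 5 were tested, and CRA1, CRU2, CRU3 and SESA1 to SESA5 were not among them. Of the storage protein list, 5 of 5 tested members were called higher, also when adjusted over the list alone (median log2 difference 3.33, camera adjusted p = 2.09e-07 with the preset correlation, adjusted p = 0.038 with an estimated correlation). The cupin AT1G03890 differed by 5.20 ± 0.50, AT2G28490 by 3.42 ± 0.22 and PAP85 (AT3G22640), a vicilin-type protein, by 3.33 ± 0.32. Of 9 genes of late embryogenesis abundant (LEA) and desiccation proteins, which accumulate before drying, 8 were higher, as were 8 adjusted over the list alone (median 2.98, adjusted p = 2.2e-06, adjusted p = 0.0782 with an estimated correlation). AT5G44310 rose to 50150 ± 4711 against 144.4 ± 12.6 in chalazal seed coat. Of 4 photosynthesis genes 3 were higher, and 3 adjusted over the list alone (median 1.51, adjusted p = 0.0216, and adjusted p = 0.19 with an estimated correlation). Among them were PSAE-1 (AT4G28750) of photosystem I (1.93 ± 0.26) and PSBW (AT2G30570) of photosystem II (1.91 ± 0.39). LHCB4.1 (AT5G01530), an antenna protein (1.12 ± 0.26), dropped to 0.94 without embryo replicate 2, with an adjusted p of 0.092.

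Proteases of cell death and sugar transporters were low in the embryo. Of 7 genes of cell death and vacuolar proteases, 6 were called lower and 1 higher, and the same numbers adjusted over the list alone (median -5.21, adjusted p = 1.64e-06, adjusted p = 0.0541 with an estimated correlation). They included scpl48 (AT3G45010), a serine carboxypeptidase-like protein (-5.82 ± 0.29), and DELTA-VPE (AT3G20210), a vacuolar processing enzyme known from dying seed coat layers (-5.37 ± 0.37, at least 41.4-fold). Of 3 measured transport genes, 2 were lower and 2 adjusted over the list alone (median -4.29, adjusted p = 0.00082, and adjusted p = 0.0541 with an estimated correlation). These were SAG29 (AT5G13170), also named SWEET15 (-4.80 ± 0.34), and SWEET11 (AT3G48740) (-4.29 ± 0.35), both sucrose exporters. Of 4 mucilage genes 2 were lower, and 2 adjusted over the list alone (median -1.37, adjusted p = 0.0326, adjusted p = 0.197 with an estimated correlation), and 1 was called without either embryo replicate. In all, 3601 probe sets were called, 1792 higher and 1809 lower, of which 3222 differed by at least 1 on the log2 scale. The number was 1855 without embryo replicate 1 and 2065 without embryo replicate 2. Against each other compartment separately, 216 probe sets were higher in the embryo. With no floor 127 were left, 86 and 120 without embryo replicates 1 and 2, and 133 and 137 without peripheral endosperm replicates 1 and 2.

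**Figure D1:**
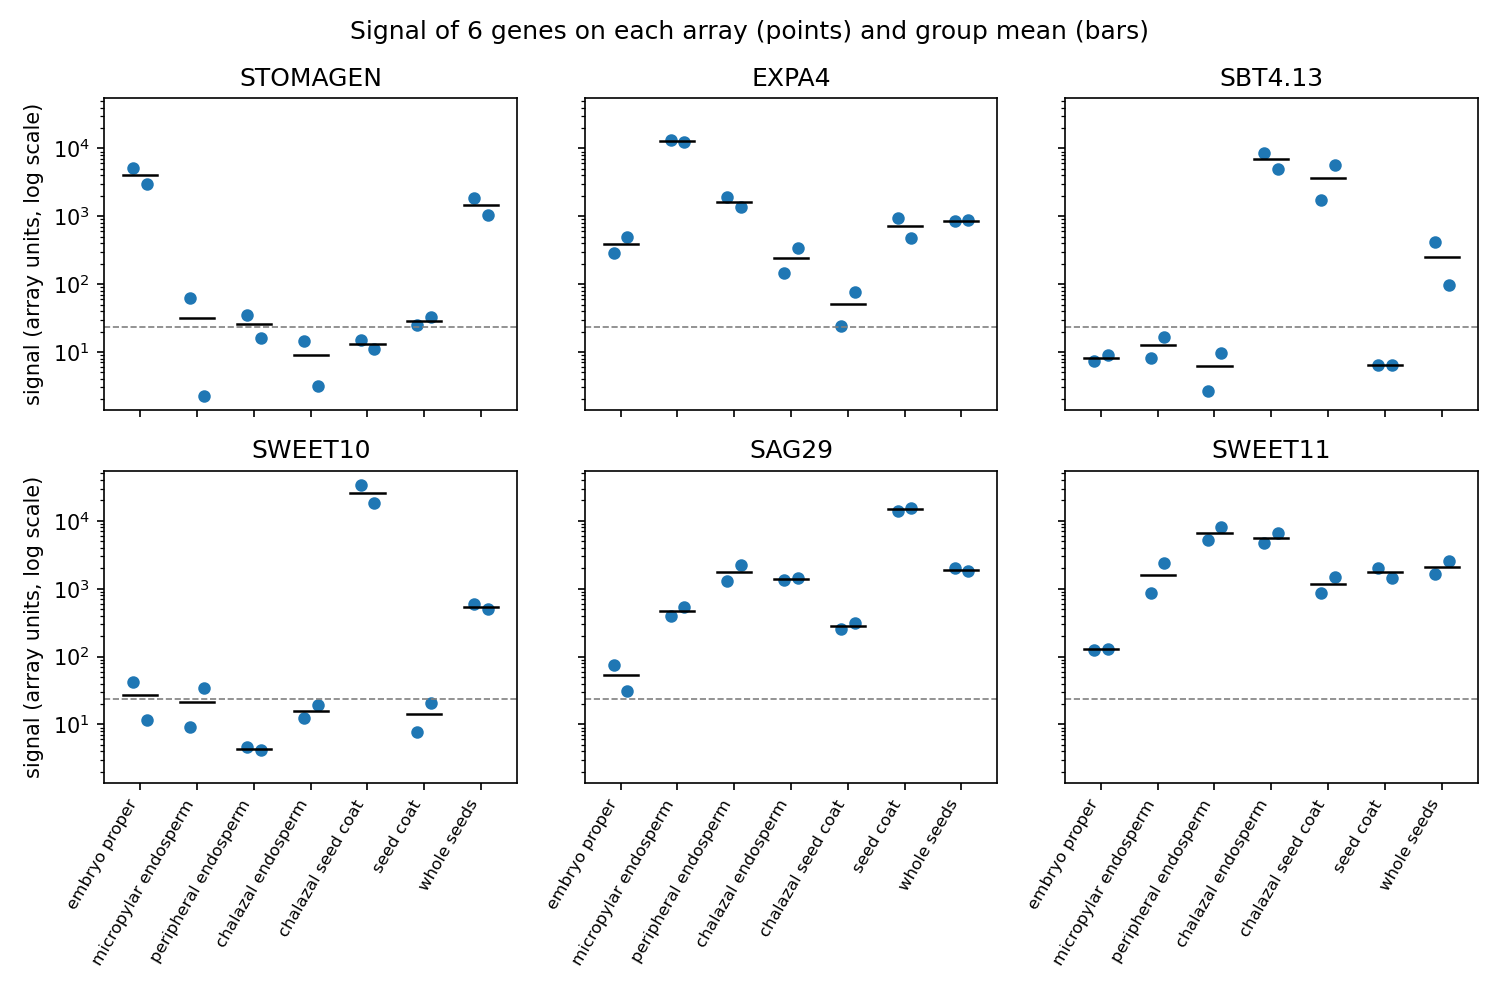
Signals of 6 genes in each of the 14 arrays on a log axis of array intensity (arbitrary units), with points for single arrays, bars for group means and a dashed line for the floor of 23.4. STOMAGEN stood highest in embryo, EXPA4 in micropylar endosperm, SBT4.13 in chalazal endosperm and chalazal seed coat, SWEET10 in chalazal seed coat, SAG29 in seed coat, and SWEET11 was lowest in embryo.

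The micropylar endosperm, the cap over the root tip that the root later breaks through, was compared with the mean of the other 5 compartments. EXPA4 (AT2G39700), an expansin, which loosens walls, had a signal of 12680 ± 587 there, 1641 ± 364 in peripheral endosperm and 50.9 ± 37.3 to 706 ± 318 in the remaining compartments. Its log2 difference was 5.26 ± 0.43 (adjusted p = 7.8e-06). AT1G04645 was at least 104.7-fold higher (6.71 ± 0.71, adjusted p = 4e-05). TBL36 (AT3G54260), of a family that acetylates wall polysaccharides (4.88 ± 0.54, at least 29.45-fold), the tetraspanins TET4 (AT5G60220) (4.88 ± 0.47, at least 29.44-fold) and TET3 (AT3G45600) (3.10 ± 0.33), XTH32 (AT2G36870), a xyloglucan endotransglucosylase (3.59 ± 0.47), DI21 (AT4G15910), a drought-induced gene (4.33 ± 0.35), and SDT (AT2G23510), which makes disinapoyl spermidine (2.99 ± 0.34), were higher as well. LBD16 (AT2G42430), a transcription factor of lateral root formation, was 4.1 ± 0.72 higher (adjusted p = 0.0016), with an adjusted p of 0.051 without micropylar endosperm replicate 1. Lower values were called for TBL38 (AT1G29050) (-3.60 ± 0.47) and the beta-glucosidase BGLU40 (AT1G26560) (-3.53 ± 0.53, 1 array at the floor).

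Both reserve lists lay above the mean of the other 5 compartments in the micropylar endosperm. That mean includes chalazal seed coat, where the medians were -4.80 for storage protein and -5.64 for LEA genes. Of 5 storage protein genes 4 were higher, and 4 adjusted over the list alone (median 1.7, adjusted p = 1.28e-05, and adjusted p = 0.0444 with an estimated correlation). Of 9 LEA genes 7 were higher, and 7 adjusted over the list alone (median 2.55, adjusted p = 3.2e-06, adjusted p = 0.0782 with an estimated correlation), and 3 were called without micropylar endosperm replicate 1. Of 7 genes of cell death and vacuolar proteases 5 were higher, and 5 adjusted over the list alone (median 1.58, adjusted p = 0.000317, and adjusted p = 0.098 with an estimated correlation), and 2 were called without either micropylar replicate. ALPHA-VPE (AT2G25940), a vacuolar processing enzyme of vegetative organs, stood at 7996 ± 3903 against 133.6 ± 98.3 in the embryo. The mean of the other 5 compartments includes the embryo, where the protease median was -5.21, which raises the protease differences elsewhere. Of 4 mucilage genes 1 was lower, and 4 adjusted over the list alone (median -1.08, adjusted p = 0.0183, adjusted p = 0.18 with an estimated correlation). That count was 0 with no floor, with spike-in scaling and without any array but embryo replicate 1, chalazal seed coat replicate 1 or seed coat replicate 2. In all 1642 probe sets were called, 877 higher and 765 lower (53.4% higher), against 1004 with no filter, 370 without micropylar endosperm replicate 1 and 536 without replicate 2. With each array divided by its median, which moved the median difference of all probe sets by 0.21, 69.2% of 1903 calls were higher, and with spike-in scaling, chosen after the data were seen, which moved it by 0.32, 76.2% of 2048. Against each other compartment separately 9 probe sets were higher. The number was 2 with no floor, 5 with no filter, 5 with the compartment arrays alone, 4 without embryo replicate 1, 1 and 2 without micropylar endosperm replicates 1 and 2, 2 and 3 without peripheral endosperm replicates 1 and 2, and 5 without either whole-seed replicate.

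The peripheral endosperm, the cell layer around the embryo, shared leading genes with the micropylar endosperm. XTH32 had 3587 ± 180 in peripheral and 2571 ± 243 in micropylar endosperm (4.17 ± 0.47 above the mean of the other 5 compartments, adjusted p = 9.8e-05), and AT3G29190 6375 ± 2677 and 5140 ± 203 (5.26 ± 0.63, at least 38.21-fold, adjusted p = 0.00013). ALPHA-VPE reached 13040 ± 1923 (3.40 ± 0.38, adjusted p = 8.6e-05) and SWEET11 6627 ± 1999 (2.50 ± 0.35, adjusted p = 0.00048). AT4G38410 (4.49 ± 0.48) and AT3G17640 (3.90 ± 0.46, at least 14.9-fold) were higher too. Among the lower genes were AT1G73120 (-4.34 ± 0.50, at least 20.29-fold, adjusted p = 0.00011) and AT5G07820 (-4.01 ± 0.48, 1 array at the floor). The receptor kinase EMS1 (AT5G07280) was 2.52 ± 0.46 higher (adjusted p = 0.003), with an adjusted p of 0.08 without peripheral endosperm replicate 1 and 0.078 without replicate 2. For 9 of the 41 named genes called, both arrays lay beyond every array of the other 5 compartments.

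Of the storage protein list 5 of 5 tested genes were higher in peripheral endosperm, also adjusted over the list alone (median 1.97, adjusted p = 6.39e-07, and adjusted p = 0.038 with an estimated correlation), such as AT2G28490 (2.06 ± 0.22), and 3 without peripheral endosperm replicate 1. Among 9 LEA genes 5 were higher, and 6 adjusted over the list alone (median 1.64, adjusted p = 9.64e-06, and adjusted p = 0.0847 with an estimated correlation), but 0 without peripheral endosperm replicate 1. Of 4 photosynthesis genes 2 were higher, and 4 adjusted over the list alone (median 0.97, adjusted p = 0.00329, adjusted p = 0.148 with an estimated correlation). With spike-in scaling PSBW moved from 1.04 to 1.61 and LHCB4.1 from 0.89 to 1.45. The count called was 0 without either peripheral replicate, 4 with spike-in scaling, and 1 with no floor, with quantile normalization and without embryo replicate 1, micropylar replicate 2, chalazal endosperm replicate 1 or either whole-seed replicate. Of 7 genes of cell death and vacuolar proteases 4 were higher, and 5 higher and 1 lower adjusted over the list alone (median 1.23, adjusted p = 0.000755, adjusted p = 0.115 with an estimated correlation), with 2 and 1 called higher without peripheral endosperm replicates 1 and 2. SWEET11 and SAG29 were the 2 transport genes of 3 called higher, and 2 were so adjusted over the list alone (median 1.35, adjusted p = 0.036, adjusted p = 0.148 with an estimated correlation and 0.0803 with spike-in scaling), with 1 called without either peripheral replicate. SAG29, 1.35 ± 0.34 higher, dropped to 0.95 without peripheral endosperm replicate 2 (adjusted p = 0.35) and stood at 1.74 without replicate 1 (adjusted p = 0.08). For proteases and transport genes the mean of the other 5 compartments includes the embryo (medians -5.21 and -4.29), which raises the differences elsewhere. For mucilage genes it includes seed coat (median 3.01) and chalazal seed coat (2.20), which lowers them. With spike-in scaling the mucilage genes AT2G22900 and ARA12 moved from -1.27 to -0.70 and from -0.65 to -0.09. Of 4 mucilage genes 2 were lower, and 2 adjusted over the list alone (median -0.96, adjusted p = 0.0238, adjusted p = 0.188 with an estimated correlation and 0.0737 with no floor). That count was 0 without either peripheral replicate, and 1 with no floor, with spike-in scaling and without either embryo replicate, micropylar replicate 2 or either whole-seed replicate.

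In all 1378 probe sets were called in peripheral endosperm, 783 higher and 595 lower (56.8% higher). No filter gave 829, and 214 and 247 were called without peripheral endosperm replicates 1 and 2. With spike-in scaling 86.9% of 3053 calls were higher and the median difference of all probe sets moved by 0.55. Division by the median moved it by 0.12. Against each other compartment separately, limma gave 0 probe sets higher in peripheral endosperm, and 3 at an unadjusted p under 0.05.

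Micropylar and peripheral endosperm were compared directly to find what separates these neighbouring parts of the same tissue. TBL36 was at least 6.11 ± 0.70 higher in the micropylar part (1893 ± 1292 against 13.3 ± 16.0, 1 array at the floor, adjusted p = 6e-04), and this call was kept without any of the 14 arrays. AT1G04645 was at least 166.5-fold higher (7.38 ± 0.92, adjusted p = 0.0013), with an adjusted p of 0.05 without micropylar endosperm replicate 1. EXPA4 was 2.97 ± 0.56 higher (adjusted p = 0.032). Its call ended with no floor (adjusted p = 0.065), with spike-in scaling (0.053), without embryo replicate 1 (0.051), either micropylar replicate (0.34 and 0.17), either peripheral replicate (0.17 and 0.35) or either whole-seed replicate (0.071 and 0.069). In the other direction, AT5G12110 had a log2 difference of -5.51 ± 0.77 (adjusted p = 0.0028), with 0.087 without micropylar endosperm replicate 1 and 0.11 without peripheral endosperm replicate 2, and AT3G05190 of -4.39 ± 0.59 (adjusted p = 0.0026), with 0.08 without peripheral endosperm replicate 2.

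Of the lists, transport genes lay lower in the micropylar than in the peripheral endosperm. None of the 3 was called, and 2 were lower adjusted over the list alone (median -1.88, adjusted p = 0.000252, and adjusted p = 0.0504 with an estimated correlation). SWEET11 had -2.18 ± 0.45 (adjusted p = 0.057) and SAG29 -1.88 ± 0.44 (0.099). The count called was 2 with spike-in scaling and 1 without embryo replicate 2 or micropylar replicate 2. Of 4 fatty acid synthesis genes 0 were called and 2 were lower adjusted over the list alone (median -1.05, adjusted p = 0.00823, and adjusted p = 0.0847 with an estimated correlation). The acyl-ACP thioesterase FaTA (AT3G25110) had -1.57 ± 0.48. Of 4 photosynthesis genes 0 were called and 1 was lower adjusted over the list alone (median -0.69, adjusted p = 0.0103, adjusted p = 0.175 with an estimated correlation). For single genes limma called 43 probe sets, 22 higher and 21 lower, and 1074 had an unadjusted p under 0.05. The count was 20 with no floor, 18 with no filter, 25 with no intensity trend and 100 with the arrays of both groups alone. Without single arrays it was 28 (embryo replicate 1), 11 and 23 (micropylar replicates 1 and 2), 19 and 8 (peripheral replicates 1 and 2), and 22 and 24 (whole-seed replicates 1 and 2). Spike-in scaling moved the median difference of all probe sets by -0.19.

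In the chalazal endosperm, the nutrient-receiving end of the tissue, a subtilase and a glucosinolate enzyme stood out. SBT4.13 (AT5G59120), a subtilisin-like protease, had 6868 ± 2583 there and 3716 ± 2812 in chalazal seed coat, and was below the floor in the other 4 compartments (6.73 ± 0.59, at least 106.1-fold, adjusted p = 5.5e-06). CYP79A2 (AT5G05260), which starts the synthesis of benzylglucosinolate from phenylalanine, had 2858 ± 1543 and 808 ± 211 in the same tissues (5.20 ± 0.52, at least 36.85-fold, adjusted p = 1.4e-05). The transcription factors AGL79 (AT3G30260), of the MADS family (4.16 ± 0.65, at least 17.92-fold), and NGA4 (AT4G01500), of the NGATHA family (3.73 ± 0.57, at least 13.29-fold), were higher, as were AT5G57500 (4.43 ± 0.58, at least 21.62-fold), GH9C1 (AT1G48930), an endoglucanase (4.49 ± 0.73, at least 22.54-fold), and B160 (AT4G21430) (2.59 ± 0.34). TET11 (AT1G18520), a tetraspanin, was 3.58 ± 0.58 higher (adjusted p = 0.00076), with 2.53 and an adjusted p of 0.063 without chalazal endosperm replicate 1. Lower values were called for TBL38 (-3.65 ± 0.47), LPR1 (AT1G23010), a ferroxidase of the phosphate response (-3.25 ± 0.57, 1 array at the floor), and FMO (AT1G12200), a flavin monooxygenase (-3.22 ± 0.35).

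The reserve lists were not called in the chalazal endosperm against the mean of the other 5 compartments, and proteases lay above it. The median was 0.13 for 9 LEA genes (adjusted p = 0.995) and -0.12 for 5 storage protein genes (adjusted p = 0.815), with 0 calls in either list. Adjusted over the list alone, 0 LEA genes were called, and 1 storage protein gene was higher and 1 lower. The storage median had the other sign with quantile normalization (0.06) and spike-in scaling (0.07). Of 7 genes of cell death and vacuolar proteases 4 were higher, and 4 higher and 1 lower adjusted over the list alone (median 1.68, adjusted p = 0.00467, and adjusted p = 0.155 with an estimated correlation). AT4G04460, an aspartic protease, reached 45820 ± 4630 and scpl48 23460 ± 398. The embryo, with a protease median of -5.21, is part of the mean compared with, which raises the protease differences here. Of 4 mucilage genes 3 were lower, and 3 adjusted over the list alone (median -1.51, adjusted p = 0.0106, adjusted p = 0.165 with an estimated correlation). That count was 1 with no floor, with spike-in scaling and without embryo replicate 2, either micropylar replicate, either peripheral replicate, chalazal endosperm replicate 2 or chalazal seed coat replicate 2. It was 0 without chalazal endosperm replicate 1. In all 1830 probe sets were called, 962 higher and 868 lower (52.6% higher), against 1199 with no filter and 540 and 1153 without chalazal endosperm replicates 1 and 2. With spike-in scaling 66.0% of 1844 calls were higher, and the median difference of all probe sets moved by 0.18. Against each other compartment separately 34 probe sets were higher. The number was 13 with no floor, 22 with no filter, 20 without embryo replicate 2, 11 and 15 without micropylar replicates 1 and 2, 9 and 10 without peripheral replicates 1 and 2, and 2 without chalazal endosperm replicate 1.

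Within the endosperm, the chalazal part was then set against the mean of the micropylar and peripheral parts. SBT4.13 was at least 282.6-fold higher (8.14 ± 0.66, adjusted p = 1.5e-06), AT1G76290 at least 345.5-fold (8.43 ± 0.69, adjusted p = 1.5e-06), and CYP79A2 5.87 ± 0.58 higher on the log2 scale (adjusted p = 1.1e-05). AGL79 (5.13 ± 0.73, at least 35.04-fold), NGA4 (4.50 ± 0.64, at least 22.69-fold) and TOPII (AT3G23890), a topoisomerase (3.61 ± 0.63), were also higher. Lower values were called for EXPA4 (-4.33 ± 0.48, adjusted p = 3.5e-05), EXPA15 (AT2G03090) (-3.51 ± 0.47) and XTH32 (-3.89 ± 0.53), along with LBD16 (-5.55 ± 0.80), the tetraspanin TET15 (AT5G57810) (-3.81 ± 0.39) and UGT84A1 (AT4G15480), a sinapate glucosyltransferase (-3.82 ± 0.69, 1 array at the floor). Of 5 storage protein genes 3 were lower, and 4 adjusted over the list alone (median -1.58, adjusted p = 8.91e-05, and adjusted p = 0.0504 with an estimated correlation). AT2G28490 stood at 2859 ± 347 against 12640 ± 2443 in micropylar and 14020 ± 5032 in peripheral endosperm. Among 9 LEA genes 4 were lower, and 7 adjusted over the list alone (median -1.58, adjusted p = 0.000117, adjusted p = 0.119 with an estimated correlation), with 2 called with quantile normalization and without micropylar replicate 2 or peripheral replicate 1, and 1 without chalazal endosperm replicate 2. In all 1325 probe sets were called, 651 higher and 674 lower (49.1% higher), with 493 without chalazal endosperm replicate 1 and 796 without peripheral endosperm replicate 1. With spike-in scaling, which moved the median difference of all probe sets by -0.20, 34.9% of 1463 calls were higher. Division by the median moved it by -0.10.

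The chalazal seed coat, the maternal tissue at the attachment point, held some of the largest differences. SWEET10 (AT5G50790), a sugar transporter, had 26220 ± 11260 there, at most 27.1 ± 21.9 in any other compartment and 541.2 ± 64.5 in whole seeds (9.92 ± 0.51, at least 966.4-fold, adjusted p = 1.7e-09). RR22 (AT3G04280), a two-component response regulator, had 21080 ± 3563 (7.42 ± 0.68), AT1G62480 43780 ± 2012 (7.91 ± 0.34, adjusted p = 2.9e-10) and ATSPS4F (AT4G10120), a sucrose phosphate synthase, 14080 ± 103 (6.71 ± 0.40). HAT2 (AT5G47370), a homeodomain-leucine zipper factor of auxin responses, was at least 212.7-fold higher (7.73 ± 0.85). Also higher were scpl31 (AT1G11080), a serine carboxypeptidase-like protein, at least 142-fold (7.15 ± 0.55), PME61 (AT3G59010), a pectin methylesterase, at least 93.22-fold (6.54 ± 0.71), and the transcription factor bZIP44 (AT1G75390) 4.90 ± 0.30 on the log2 scale. The flavonoid list had 2 of 3 measured genes higher, and 2 adjusted over the list alone (median 4.07, adjusted p = 0.043, adjusted p = 0.175 with an estimated correlation and 0.104 with no floor). They were BAN (AT1G61720), anthocyanidin reductase of the tannin pathway, at 773 ± 588 (4.58 ± 0.59, at least 23.91-fold), and DFR (AT5G42800), dihydroflavonol reductase, at 1920 ± 1397 (4.07 ± 0.58). Of 4 mucilage genes 3 were higher, and 3 adjusted over the list alone (median 2.20, adjusted p = 0.0166, and adjusted p = 0.18 with an estimated correlation).

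Reserve and photosynthesis transcripts were low in the chalazal seed coat. Of the storage protein list 5 of 5 tested genes were lower, also adjusted over the list alone (median -4.80, adjusted p = 9.1e-08, and adjusted p = 0.038 with an estimated correlation). PAP85 stood at 317.2 ± 62.5 against 57050 ± 31990 in the embryo. Of 9 LEA genes 7 were lower, and 7 adjusted over the list alone (median -5.64, adjusted p = 2.09e-07, and adjusted p = 0.0566 with an estimated correlation). Lowest were AT2G42560 (-8.24 ± 0.58, adjusted p = 4.4e-08) and AtLEA4-1 (AT1G32560) (-6.62 ± 0.52). Of 4 photosynthesis genes 3 were lower, and 4 adjusted over the list alone (median -2.17, adjusted p = 0.0013, and adjusted p = 0.121 with an estimated correlation), such as PSAE-1 (-3.25 ± 0.26). In all 4634 probe sets were called, 2233 higher and 2401 lower, and 2570 without chalazal seed coat replicate 1. Spike-in scaling moved the median difference of all probe sets by 0.16. Against each other compartment separately 277 probe sets were higher. The number was 174 with no floor, 135 without chalazal seed coat replicate 1, 487 with spike-in scaling and 909 with both seed coat arrays left out, the latter 2 chosen after the data were seen.

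The seed coat outside the chalazal region was compared with the mean of the other 5 compartments. AT3G14760 had 30120 ± 6541 in seed coat and 4139 ± 2641 in chalazal seed coat (8.63 ± 0.50, at least 395.4-fold, adjusted p = 3.6e-08). AT1G73600, a phosphoethanolamine methyltransferase, reached 39020 ± 4895 (7.21 ± 0.64) and AT4G36610 39710 ± 3632 (7.14 ± 0.54). SAG29 had 14830 ± 1185 against 53.4 ± 32.3 in the embryo and 284.3 ± 45.1 in chalazal seed coat (5.11 ± 0.34, adjusted p = 1.3e-07). UGT71B1 (AT3G21750), a glucosyltransferase (4.70 ± 0.47), cdc2cAt (AT5G39420), a cyclin-dependent kinase (4.78 ± 0.59, at least 27.47-fold), XEG113 (AT2G35610), an arabinosyltransferase of extensins (3.24 ± 0.33), APM1 (AT4G33090), an aminopeptidase (2.69 ± 0.31), and GID1A (AT3G05120), a gibberellin receptor (2.65 ± 0.32), were higher too. With spike-in scaling the last 3 stood at 1.95, 1.41 and 1.36. PAC (AT2G48120) was lower (-3.32 ± 0.48, 1 array at the floor), and COR27 (AT5G42900), a cold-regulated gene of the clock (-3.57 ± 0.56), stood at -2.08 without seed coat replicate 1.

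Of 23 mucilage and integument loci in the list 4 were tested, and these rose together in seed coat. All 4 of 4 were called higher, also adjusted over the list alone (median 3.01, adjusted p = 0.000165, adjusted p = 0.0782 with an estimated correlation). They were ARA12 (AT5G67360), also named SBT1.7, a subtilase needed for mucilage release (15570 ± 5756, 3.31 ± 0.32), the glycosyltransferase genes AT3G10320 (3.44 ± 0.51, at least 10.85-fold) and AT2G22900 (2.64 ± 0.33), and the peroxidase gene AT3G50990 (2.70 ± 0.57, at least 6.487-fold). With spike-in scaling ARA12, AT3G10320 and AT3G50990 stood at 2.03, 2.24 and 1.43. Of 3 transport genes 1 was higher, and 2 adjusted over the list alone (median 1.32, adjusted p = 0.0388, adjusted p = 0.148 with an estimated correlation). The mean compared with includes the embryo (transport median -4.29), which raises these differences. With spike-in scaling the median member, SWEET4 (AT3G28007), stood at 0.11 and SWEET11, at 0.20 before, at -1.08 (adjusted p = 0.021). Of 9 LEA genes 6 were lower, and 6 adjusted over the list alone (median -1.91, adjusted p = 0.00082, and adjusted p = 0.155 with an estimated correlation). All 5 of 5 storage protein genes were lower, also adjusted over the list alone (median -1.67, adjusted p = 0.00041, adjusted p = 0.0565 with an estimated correlation). With spike-in scaling PAP85, the median member, stood at -2.95, and AT2G18540, at -2.23 before, at -3.51. The flavonoid list had a median of -0.63 (adjusted p = 0.82) and 0 calls. In all 4078 probe sets were called, 1994 higher and 2084 lower (48.9% higher), and 2513 without seed coat replicate 1. The split depended on the scaling, on the arrays whose spike-in signals were highest. After division by the median, 27.9% of 4836 calls were higher and the median difference of all probe sets moved by -0.41. With spike-in scaling it moved by -1.23, and 8.3% of 8575 calls were higher. Quantile normalization moved it by -0.15. Against each other compartment separately 250 probe sets were higher. The number was 143 with no floor, 154 after division by the median, 59 with spike-in scaling, 145 without chalazal seed coat replicate 1 and 115 without seed coat replicate 1.

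Within the maternal seed coat, the chalazal region was compared with the rest. SWEET10 was at least 1066-fold higher in the chalazal region (10.06 ± 0.66, adjusted p = 1.9e-07), SBT4.13 at least 134-fold (7.07 ± 0.77), TET5 (AT4G23410), a tetraspanin, at least 101-fold (6.66 ± 0.86), and LCR68 (AT2G02130), a small cysteine-rich protein of the defensin type, 5.73 ± 0.43 on the log2 scale (8656 ± 3551 against 162.6 ± 64.8, adjusted p = 5.9e-07). HAT2 (6.95 ± 1.10), scpl31 (6.21 ± 0.71) and PME61 (5.77 ± 0.91) were higher too. In the other direction lay SAG29 (-5.71 ± 0.44, adjusted p = 6.4e-07), TET15 (-4.87 ± 0.45, at least 29.31-fold), EXPA4 (-3.94 ± 0.56) and EXPA15 (-3.92 ± 0.54). Glucosinolate genes had 2 of 3 higher, and 2 adjusted over the list alone (median 2.62, adjusted p = 0.00906, and adjusted p = 0.0847 with an estimated correlation). They were the transporter GTR2 (AT5G62680) at 4679 ± 345 against 98.6 ± 83.1 (5.88 ± 0.67, adjusted p = 3.7e-05) and its paralog GTR1 (AT3G47960) (2.62 ± 0.65, adjusted p = 0.013). GTR1 stood at 1.13 without seed coat replicate 1 (adjusted p = 0.12), 4.12 without seed coat replicate 2 and 2.61 without chalazal seed coat replicate 1 (adjusted p = 0.072). The same list was not called in chalazal endosperm (median 2.33, adjusted p = 0.0876) or in chalazal seed coat (2.48, adjusted p = 0.1) against the other 5 compartments.

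Flavonoid genes had 2 of 3 higher in the chalazal region, and 2 adjusted over the list alone (median 2.83, adjusted p = 0.0246, adjusted p = 0.15 with an estimated correlation, 0.129 with no floor and 0.171 with spike-in scaling). They were BAN (4.74 ± 0.76, adjusted p = 0.00074, and 0.06 with no floor) and DFR (2.83 ± 0.75, adjusted p = 0.02). DFR had an adjusted p of 0.14 with no floor, 0.16 without chalazal seed coat replicate 2 (2.00) and 0.088 without seed coat replicate 1 (2.49). Of 5 storage protein genes 4 were lower, and 5 adjusted over the list alone (median -3.21, adjusted p = 3.48e-06, and adjusted p = 0.038 with an estimated correlation). Of 9 LEA genes 6 were lower, and 6 adjusted over the list alone (median -2.32, adjusted p = 8.91e-05, adjusted p = 0.115 with an estimated correlation). With spike-in scaling the storage proteins AT2G28490 (-3.55 ± 0.29), AT4G36700 (-3.25 ± 0.32) and PAP85 (-3.21 ± 0.41) stood at -2.34, -2.03 and -2.00. Of 4 photosynthesis genes 2 were lower, and 4 adjusted over the list alone (median -1.12, adjusted p = 0.0125, and adjusted p = 0.18 with an estimated correlation). With spike-in scaling the median was 0.09 and the adjusted p 0.114. The count called was 0 with spike-in scaling and without chalazal seed coat replicate 1, and 1 after division by the median and without either peripheral replicate, chalazal seed coat replicate 2, seed coat replicate 2 or either whole-seed replicate. In all 2122 probe sets were called, 1017 higher and 1105 lower (47.9% higher). The number was 834 with the arrays of both groups alone and 950 without chalazal seed coat replicate 1. After division by the median, which moved the median difference of all probe sets by 0.35, 70.3% of 2289 calls were higher, and with spike-in scaling, which moved it by 1.16, 94.9% of 5541.

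Both chalazal comparisons, in endosperm and in seed coat, share no array and ask whether the chalazal pole has genes in common across these tissues. The probe sets higher at the chalazal pole in both numbered 181, with 46.5 expected from independent lists, and 184 were lower in both, with 52.3 expected. Opposite calls numbered 25 (higher in endosperm, lower in seed coat, 50.5 expected) and 44 (the reverse, 48.1 expected). These 4 counts were then taken, after the data were seen, with no floor, under the 3 other scalings and with each array left out, and both shared counts exceeded the expected number in each. The 181 became 292 with spike-in scaling (188.5 expected) and 103 without chalazal endosperm replicate 1 (16 expected). The 184 became 97 with spike-in scaling (18.9 expected), 115 without micropylar replicate 1, 108 without peripheral replicate 1 and 100 without chalazal endosperm replicate 1. The 25 became 14 with no floor, 10 after division by the median, 4 with spike-in scaling, 15 without peripheral replicate 1, 11 and 10 without chalazal endosperm replicates 1 and 2, 8 without chalazal seed coat replicate 1, 15 and 12 without seed coat replicates 1 and 2, and 15 without either whole-seed replicate. The 44 became 76 after division by the median, 276 with spike-in scaling, 26 without peripheral replicate 1, 23 without chalazal endosperm replicate 1 and 21 without chalazal seed coat replicate 1. Across the 14252 probe sets the differences had a Pearson correlation of 0.29 and a Spearman correlation of 0.204. Among shared genes, picked after their values were seen, were SBT4.13 (at least 8.14 ± 0.66 in endosperm and at least 7.07 ± 0.77 in seed coat), CYP79A2 (5.87 ± 0.58 and at least 5.08 ± 0.67), NGA4 (at least 4.50 ± 0.64 and at least 2.70 ± 0.73), GTR2 (2.95 ± 0.58 and 5.88 ± 0.67) and MYC3 (AT5G46760), a transcription factor that controls glucosinolate genes (1.61 ± 0.35 and 2.01 ± 0.41). Calls ended for GTR2 in endosperm without chalazal endosperm replicate 1 (2.63, adjusted p = 0.081), for MYC3 in endosperm without replicate 2 (1.30, adjusted p = 0.11), and for NGA4 in seed coat without chalazal seed coat replicate 2 (2.26, adjusted p = 0.12) or seed coat replicate 2 (2.42, adjusted p = 0.085).

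**Figure D2:**
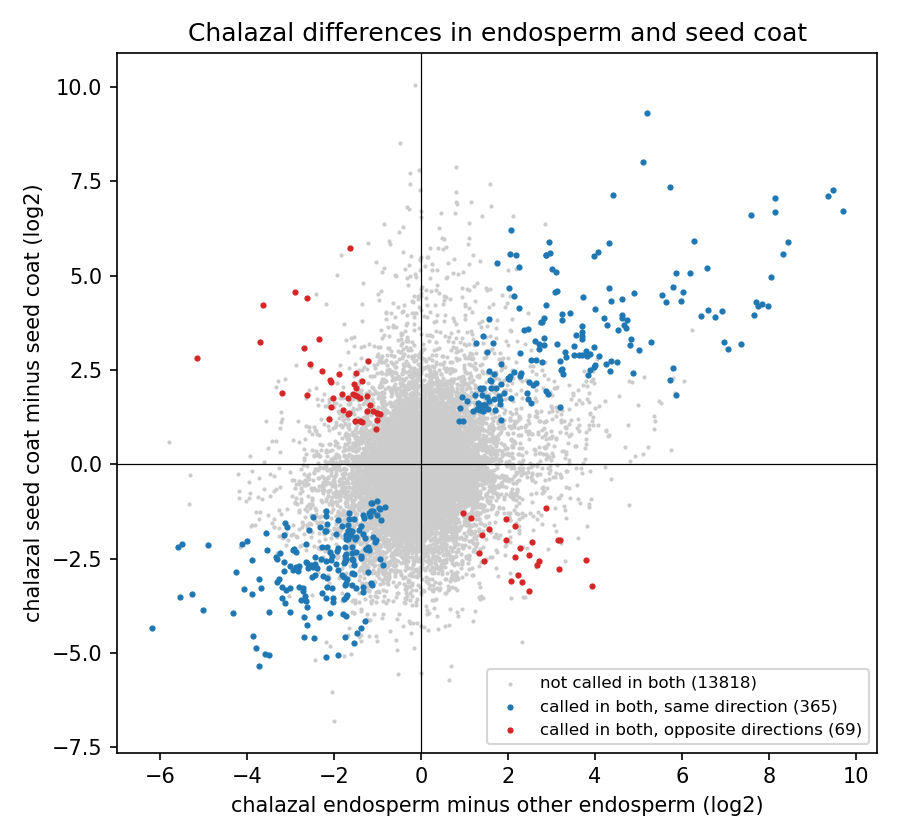
Each point is a probe set, with the log2 difference of chalazal against other endosperm on the x axis and that of chalazal seed coat against seed coat on the y axis. Colours mark the 365 called in both with the same sign, the 69 called in both with opposite signs and the 13818 others.

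Whole seeds were compared with the embryo to show what the maternal tissues and the endosperm add. AT1G62070, at 101900 ± 12820 in seed coat, had 21190 ± 3153 in whole seeds and 40.5 ± 18 in the embryo (9.10 ± 1.29, adjusted p = 0.00035). AT3G14760 was at least 120.8-fold higher in whole seeds (6.92 ± 0.65), SAG29 5.31 ± 0.44 on the log2 scale (adjusted p = 2.5e-06), ALPHA-VPE 4.75 ± 0.49, SWEET7 4.55 ± 0.41 (at least 23.44-fold), scpl48 4.40 ± 0.38, the expansin-like gene EXLA1 (AT3G45970) 4.25 ± 0.50 and SWEET11 4 ± 0.45. Transport genes had 2 of 3 higher, and 2 adjusted over the list alone (median 4, adjusted p = 9.64e-06, and adjusted p = 0.038 with an estimated correlation). Cell death and vacuolar proteases had 5 of 7 higher, and 6 higher and 1 lower adjusted over the list alone (median 3.21, adjusted p = 5.8e-07, and adjusted p = 0.0504 with an estimated correlation). Mucilage genes had 1 of 4 higher, and 1 adjusted over the list alone (median 0.95, adjusted p = 0.0358, and adjusted p = 0.202 with an estimated correlation).

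Desiccation transcripts were lower in whole seeds than in the embryo. Of 9 LEA genes 6 were lower, and 7 adjusted over the list alone (median -2.77, adjusted p = 2.1e-08, adjusted p = 0.0504 with an estimated correlation), with 2 called without embryo replicate 2 or whole-seed replicate 2 and 3 without whole-seed replicate 1. AT3G02480 fell from 44420 ± 4806 in the embryo to 3082 ± 1071 (-3.89 ± 0.57, adjusted p = 0.00044) and AT4G21020 from 23500 ± 936 to 2625 ± 164 (adjusted p = 0.00018). AT2G42560 was -3.89 ± 0.74 (adjusted p = 0.0049), with -2.75 and an adjusted p of 0.091 without embryo replicate 2, and -3.72 and 0.064 without whole-seed replicate 2. Of 5 storage protein genes 1 was lower, and 2 adjusted over the list alone (median -0.86, adjusted p = 0.000922, adjusted p = 0.0666 with an estimated correlation), with 0 called without embryo replicate 1 or either whole-seed replicate and 2 without either chalazal seed coat replicate. The oleosin gene OLEO3 (AT5G51210) had 76740 ± 16210 in the embryo and 71650 ± 7728 in whole seeds (-0.09 ± 0.42, adjusted p = 0.97). Outside the reserves, OBE1 (AT3G07780), a PHD finger protein of meristems, was lower (-2.10 ± 0.27, adjusted p = 0.00014), with 2294 ± 185 in whole seeds and 6195 ± 477 to 12330 ± 2388 in the 6 compartments, as was SPPA (AT1G73990), a plastid protease (-1.99 ± 0.34, adjusted p = 0.002). OBE1 was among 10 of 14252 probe sets called lower, by at least 1 on the log2 scale, in whole seeds than in each compartment. In the other direction 1 was called. A mixture of the 6 compartments gives no value outside their range at the scaling used, and the cause was not tested. In all 684 probe sets were called, 504 higher and 180 lower (73.7% higher). The number was 432 with no filter, 423 and 392 without embryo replicates 1 and 2, and 253 and 289 without whole-seed replicates 1 and 2. After division by the median, which moved the median difference of all probe sets by -0.24, 55.5% of 703 calls were higher.

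**Figure D3:**
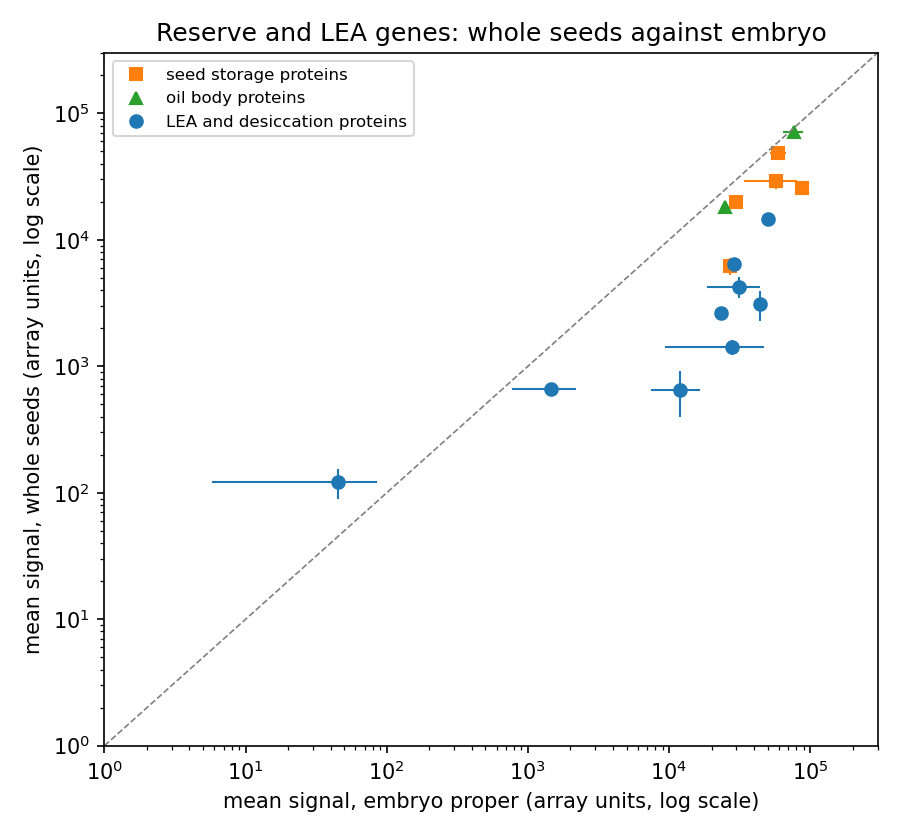
Mean signal in whole seeds against mean signal in the embryo (array intensity, both axes logarithmic) for the tested storage protein, oil body and LEA genes, with lines for the range of the 2 arrays and a dashed line where both are equal. OLEO3 lies near the line, and LEA genes such as AT3G02480 lie far below it.

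Across probe sets, again no independent replicates, the whole-seed profile lay nearest to that of the embryo. The Pearson correlation of mean log2 signals was 0.851 with embryo, 0.827 with peripheral endosperm, 0.798 with micropylar endosperm, 0.735 with chalazal endosperm, 0.671 with seed coat and 0.569 with chalazal seed coat, and the Spearman correlations were 0.845, 0.816, 0.786, 0.734, 0.660 and 0.574.

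Several lists had fewer than 3 genes tested and were read gene by gene. For oil bodies, OLEO3 was higher in the embryo (2.91 ± 0.33, adjusted p = 7.9e-06) and lower in chalazal seed coat (-4.83 ± 0.33, adjusted p = 3.4e-08). There AT3G01570, another oleosin, stood at 106 ± 132 against 24840 ± 1359 in the embryo (-6.79 ± 0.49 against the other 5 compartments, adjusted p = 6.2e-08). For lipid mobilisation, ICL (AT3G21720), isocitrate lyase of the glyoxylate cycle, had 4274 ± 1675 in the embryo (3.49 ± 0.59, adjusted p = 4e-04), and SDP1 (AT5G04040), a triacylglycerol lipase, was lower in the embryo (-1.28 ± 0.29, adjusted p = 0.0039). Among maturation regulators, the bZIP factor EEL (AT2G41070) was higher in the embryo (1.82 ± 0.22, adjusted p = 1.9e-05) and lower in seed coat (-2.72 ± 0.22, adjusted p = 7.3e-07), and BZIP53 (AT3G62420) was higher in chalazal seed coat (7153 ± 562, 1.57 ± 0.21, adjusted p = 3.5e-05). PRL (AT4G02060), the replication helicase subunit MCM7 and the measured member of the cell division list, was higher in chalazal endosperm (2.26 ± 0.60, adjusted p = 0.021) and lower in seed coat (-2.87 ± 0.60, adjusted p = 0.0019). These calls ended without chalazal endosperm replicate 1 (1.65, adjusted p = 0.31) and without seed coat replicate 1 (-2.15, adjusted p = 0.06). Of the endosperm markers, AGL62 (AT5G60440) and IKU2 (AT3G19700) were measured but too dim to be tested, with at most 109.9 ± 24.7 and 115.8 ± 32.4, both in seed coat tissues, as were the expansins EXPA8 (AT2G40610) and EXPA9 (AT5G02260) and the heat shock gene AT1G53540. Lists for embryo patterning, vascular tissue, suberin and cutin, gibberellin and abscisic acid metabolism had 0 members on probe sets with a name, so these markers were not analysed here.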

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

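The comparisons below and their alternatives were chosen after the results of both chalazal comparisons had been seen. They were picked out because the difference between the chalazal part and the rest was not the same in the endosperm and in the seed coat.

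In the interaction contrast of limma, 878 of 14252 probe sets had a chalazal difference that differed between endosperm and seed coat. Of the probe sets called in both comparisons, 69 had opposite signs. The 878 became 555 with no floor, 3998 with spike-in scaling, 524 without peripheral endosperm replicate 1, 410 without chalazal endosperm replicate 1 and 462 without chalazal seed coat replicate 1. The 69 became 280 with spike-in scaling, 41 without peripheral endosperm replicate 1, 34 and 42 without chalazal endosperm replicates 1 and 2 and 29 without chalazal seed coat replicate 1. LCR68, a defensin-type protein, was lower in chalazal than in other endosperm (-1.63 ± 0.37, adjusted p = 0.011) and higher in chalazal seed coat than in seed coat (5.73 ± 0.43), with an adjusted p of 5e-06 for the difference. AT5G45920 went the same way (-5.15 ± 0.38 and 2.83 ± 0.44, adjusted p = 4.1e-06 for the difference). BGLU44, a beta-glucosidase, was higher in chalazal endosperm (3.16 ± 0.70) and lower in chalazal seed coat (-2.78 ± 0.81, adjusted p = 0.0047 for the difference), as was DPL1, a sphingolipid lyase (1.94 ± 0.31 and -1.45 ± 0.35, adjusted p = 0.00068 for the difference).

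For these 4 genes the difference was called in every setting run (no floor, the 3 other scalings, each array left out), but single calls ended. LCR68 had adjusted p = 0.068 and 0.079 in endosperm without chalazal endosperm replicates 1 and 2. BGLU44 had 0.058 and 0.1 there without them. In seed coat it stood at -1.57 with spike-in scaling (adjusted p = 0.11) and -1.27 without chalazal seed coat replicate 1 (0.38), and had 0.11 and 0.081 without seed coat replicates 1 and 2. DPL1 in seed coat stood at -1.08 after division by the median (adjusted p = 0.059) and -0.24 with spike-in scaling (0.66), and had 0.078 without chalazal seed coat replicate 1 and 0.054 without seed coat replicate 2.

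For 2 reserve genes the chalazal value lay below in both tissues by different amounts, called in both for AT2G28490 and in seed coat for AT2G42560. The LEA gene AT2G42560 had -2.05 ± 0.64 in endosperm (adjusted p = 0.057) and -6.04 ± 0.74 in seed coat (adjusted p = 7.6e-05), a difference of 3.99 (adjusted p = 0.026). The call on the difference ended with no floor (4.89, adjusted p = 0.056), with spike-in scaling (2.63, 0.052), and without micropylar replicate 1 or 2 (0.053 and 0.051), peripheral replicate 2 (0.056), chalazal endosperm replicate 1 (2.98, 0.13), chalazal seed coat replicate 1 (2.81, 0.13) or seed coat replicate 2 (0.078). The storage protein gene AT2G28490 had -2.19 ± 0.25 and -3.55 ± 0.29, a difference of 1.36 (adjusted p = 0.046) that depended on the scaling. It was 0.88 after division by the median (adjusted p = 0.23), -0.07 with spike-in scaling (0.92) and 1.46 with quantile normalization (0.033). Its call ended with no floor (0.056) and without any array but peripheral endosperm replicate 1, with adjusted p up to 0.11. The cause of these differences was not tested.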

How the results depend on the processing

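The spike-in scaling, the fit without the seed coat arrays and all settings of the list member counts, the shared chalazal calls and the chalazal interaction were chosen after the data were seen, and the other alternatives before. Camera was run with an estimated correlation, no floor, no filter, the 3 other scalings and the replicate block. In none of these did a called list turn direction, although the median of the photosynthesis genes in chalazal seed coat against seed coat did turn. Camera sets members against all other probe sets. Division by the median and spike-in scaling shift nearly all probe sets of an array alike. They could therefore hardly turn a list or change the number called, and do not test the lists against scaling. Of 384 differences of named genes, 361 kept their call or its absence with no floor, 380 after division by the median, 381 with quantile normalization and 369 with spike-in scaling. Left-out arrays gave 5376 values, of which 5051 kept the call or its absence and 302 lost the call. A group with 1 array left takes its spread from the other groups. The number of called lists was 42, and 39 with no floor, 43 with no filter, with division by the median, with quantile normalization and with spike-in scaling, but 6 with an estimated correlation.

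With no floor, calls fell to 20 in micropylar against peripheral endosperm, and enriched probe sets to 127 in embryo, 2 in micropylar endosperm, 13 in chalazal endosperm, 174 in chalazal seed coat and 143 in seed coat. With no filter, which adds dim probe sets to the adjustment, calls were 1004 in micropylar, 829 in peripheral and 1199 in chalazal endosperm, 18 in micropylar against peripheral endosperm and 432 in whole seeds against embryo, and enriched probe sets 5 in micropylar and 22 in chalazal endosperm. With no intensity trend 25 were called in micropylar against peripheral endosperm. With only the arrays of the groups compared, this number was 100, chalazal seed coat against seed coat gave 834, and 5 were enriched in micropylar endosperm. Division by the median left 154 enriched in seed coat. Spike-in scaling gave 3053 calls in peripheral endosperm, 8575 in seed coat and 5541 in chalazal seed coat against seed coat, and 1 enriched in peripheral endosperm, 487 in chalazal seed coat and 59 in seed coat. Without both seed coat arrays, and so with fewer compartments to exceed, 909 were enriched in chalazal seed coat. Where no construction is named, the cause was not tested.

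With each array left out in turn, calls ranged from 1855 to 3898 in embryo, 370 to 1910 in micropylar endosperm, 214 to 1681 in peripheral endosperm, 540 to 2006 in chalazal endosperm, 2570 to 4925 in chalazal seed coat, 2513 to 4160 in seed coat, 8 to 57 in micropylar against peripheral endosperm, 493 to 1519 in chalazal against other endosperm, 950 to 2145 in chalazal seed coat against seed coat and 253 to 771 in whole seeds against embryo. The lowest came each time without an array of a group compared, which leaves 1 array there. Enriched probe sets ranged from 86 to 236 in embryo, 1 to 11 in micropylar endosperm, 0 to 0 in peripheral endosperm, 2 to 40 in chalazal endosperm, 135 to 256 in chalazal seed coat and 115 to 236 in seed coat.

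The sign turned for 5 genes, and the cause was not tested. SWEET11 in seed coat, 0.20 and not called, was -0.22 after division by the median, -0.04 and 0.45 without seed coat replicates 1 and 2, and -1.08 with spike-in scaling (adjusted p = 0.021). UGT80B1 in chalazal seed coat, 0.06 and not called, was 0 without embryo replicate 1 (just under it), -0.09 without peripheral endosperm replicate 1, -0.04 without chalazal seed coat replicate 2, and 0.55 and -0.43 without seed coat replicates 1 and 2. In chalazal seed coat against seed coat, UGT80B1 (0.57, not called) was 3.01 and -1.86 without seed coat replicates 1 and 2. BCAT4 (0.82, not called) was 2.53 and -0.9 without them, and -0.09 without chalazal seed coat replicate 2. With spike-in scaling PSBW turned there from -1.16 to 0.06 and LHCB4.1 from -1.09 to 0.12 (adjusted p = 0.81).

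The correlation of whole seeds with embryo, micropylar and peripheral endosperm was 0.826, 0.773 and 0.804 with no floor. With no filter, which adds probe sets dim in every group, it was 0.906 with embryo, 0.88 with micropylar, 0.897 with peripheral and 0.849 with chalazal endosperm, 0.778 with chalazal seed coat and 0.804 with seed coat. The order of the compartments stayed the same. On each array 16.5 to 21.9% of probe sets lay at or under the floor. This share follows from setting the floor at the 20th percentile and gives no estimate of background.

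The arrays share replicate numbers, but the labels do not say that a number marks a shared seed or day. Deviations of same-numbered arrays had correlations of -0.061 to 0.096 over 21 pairs of groups (0 over 0.1), so the numbers were not taken as pairs. With the replicate number as a block, calls were 3668, 1710, 1471, 1848, 4674 and 4121 for the 6 compartments in the order used above, and 50, 1382, 2206 and 713 for the further comparisons. Enriched probe sets were 230, 8, 0, 37, 282 and 260, and 42 lists were called.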

Other observations

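All tests of explanations in this part, and the families, were chosen after the results were seen, while the lists were planned. Genes of the plastid genome, 69 of them tested, lay above the mean of the other 5 compartments in the embryo (median 0.57, 24 called higher, adjusted p = 1.69e-07, adjusted p = 0.625 with an estimated correlation) and in micropylar endosperm (median 0.58, 13 called higher, adjusted p = 5.05e-11, adjusted p = 0.602 with an estimated correlation). In peripheral endosperm the list shifted up (median 0.38, 58 of 69 above 0, 4 called and 0 adjusted over the list alone, adjusted p = 0.00012, adjusted p = 0.704 with an estimated correlation). Spike-in scaling moved the median difference of all probe sets there by 0.55, more than that median. In chalazal seed coat 62 of 69 were lower (median -1.38, adjusted p = 2.91e-22, adjusted p = 0.561 with an estimated correlation). Against seed coat 35 were lower (median -1.09, adjusted p = 2.43e-18, adjusted p = 0.561 with an estimated correlation), but the median was 0.13 with spike-in scaling.

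Shifts of families were also called in the comparisons within a tissue. In chalazal against other endosperm the plastid genes had a median of -0.31 (adjusted p = 0.000276, adjusted p = 0.704 with an estimated correlation). In micropylar against peripheral endosperm they had 0.12 (adjusted p = 0.0465, adjusted p = 0.755 with an estimated correlation), and -0.07 with spike-in scaling. In that comparison 5 of 9 tetraspanins lay above 0 and 0 were called (median 1.29, adjusted p = 0.0404, adjusted p = 0.561 with an estimated correlation). Of 28 UDP-glycosyltransferases 20 lay below 0 and 0 were called (median -0.51, adjusted p = 0.0313, adjusted p = 0.561 with an estimated correlation). In chalazal seed coat against seed coat 7 of 8 bZIP factors lay above 0 and 3 were called (median 0.83, adjusted p = 0.0263, adjusted p = 0.561 with an estimated correlation). In all 10 of 170 family tests were called with the preset correlation and 0 with the estimated.

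Of 9 LEA genes 6 were lower in whole seeds than in the embryo (adjusted p = 0.0504 for the list with an estimated correlation), and dilution by seed coat RNA was weighed first. In a mixture of the 6 compartments fitted without the list (60.4% embryo, 23.7% peripheral endosperm, 10.6% seed coat), the median of the LEA genes lay at -2.18 on the log2 scale relative to other probe sets (-1.93 and -2.43 on the 2 arrays), more than dilution in that mixture gives. Single members ran from -3.85 to 0.61 relative to the mixture, with LEA4-5 at -0.6 and M10 above it at 0.61. Scaling between arrays left the list at -2.48 or lower under every scaling tried. For RNA degradation or 3-prime bias, 0 of 3 control genes had a 3'/5' ratio on a whole-seed array above all compartment arrays. The bound written first asked for ratios within the compartment range, which 1 of 3 met, but lower ratios go against more degradation of the whole-seed arrays as well. GAPDH ratios were 2.714 to 2.84 on the whole-seed arrays and 3.526 to 7.098 on the compartment arrays. Embryo replicate 1 had the highest actin (16.89) and GAPDH (7.098) ratios, but a low ubiquitin ratio (5.446). Whether a quality difference in this other direction adds to the LEA difference was not tested. No other explanation was tested.

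Chalazal genes were shared between chalazal endosperm and chalazal seed coat, and tissue of 1 in captures of the other was tested through abundant transcripts. Chalazal seed coat tissue in the endosperm captures made up at most 1.3% by the 10th percentile of 139 abundant transcripts. The shared genes needed 154%, a median over 177 probe sets. Of the abundant transcripts 36 stayed below 10% of that need on both arrays. Single shared genes differed in their need. SBT4.13 had 6868 ± 2583 in chalazal endosperm and 3716 ± 2812 in chalazal seed coat, but scpl31 had 157.9 ± 27.9 and 9708 ± 6216. A test of the median does not exclude carry-over for members such as scpl31. Chalazal endosperm tissue in the seed coat captures was bounded at 7.69%, while 65.1% was needed. On both arrays 93 of 162 abundant transcripts stayed below that need, 35 below 50% of it and 5 below 10%, the lowest at 3.4%, which goes against this tissue as the source of all of the pattern. The bound lies just over 10% of that need, the limit set for excluding it, so a part of the pattern cannot be told apart from it. Expression in both tissues stays open.

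Seed coat captures held storage protein and LEA signals, for instance PAP85 at 3017 ± 1118. Embryo tissue in these captures could make up at most 4.91% by the 10th percentile of 244 abundant transcripts (2.63 and 4.91% on the 2 arrays), against 7.13% needed for 16 storage protein, LEA and oil body genes. On both arrays 33 of these transcripts stayed below that need, 19 below 50% of it and 3 below 10%, the lowest at no more than 0.18%, which goes against embryo tissue as the source of all of the signal. Peripheral endosperm tissue, which lies against the seed coat, could make up at most 15.5% (9.81 and 15.5%), against 13.3% needed, and 13 of 210 transcripts stayed below that need on both arrays, 1 below 50% of it and 0 below 10%, the lowest at 3.1%. Expression in the seed coat cannot be told apart from captured endosperm, or in part from captured embryo, since neither bound lies below 10% of the need.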
